A study of Mus musculus with 20 samples.

How the data were processed

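RNA from mouse bladders and metastases was measured on 20 Affymetrix whole-transcript arrays. Per the labels, RNA was extracted with a kit for fixed, paraffin-embedded tissue and converted to biotinylated sense-strand DNA before hybridisation. The deposited values are log2 expression levels, made by the authors with RMA in Affymetrix Expression Console, for which the submitters' processing notes give no versions. The base of the logarithm is not written with the values and was taken as 2 because RMA gives log2. The values ran from 2.16 to 22.0, with none missing, and 96 to 222 rows per array lay above 16, beyond what a 16-bit scanner gives on this scale; how these came about is not stated. For arrays, the number of samples limits the precision, and no count or depth exists.

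The table holds 65956 rows. The platform annotation names 32750 of them, and the 30604 rows with exactly 1 gene symbol were used, after 827 older symbols were replaced by current ones. Rows with several symbols (2146) or none (33206) were not used here. Where a symbol had several rows (355 genes), the row with the highest mean over the 20 arrays was kept, without regard to group, which left 30142 genes. Dim genes were kept.

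Samples were grouped by the labels into normal bladder (5 arrays), tumour bladder (7), treated bladder (3), metastasis (4) and palbo metastasis (1). A linear model with these groups was fitted to each gene in limma 3.58.1 under R 4.3.3, with an empirical Bayes variance, and 5 comparisons were tested on both sides with Benjamini-Hochberg adjustment over the 30142 genes and a threshold of 0.05. The lone palbo metastasis was not tested as a group. No replicate block was used, since nothing in the labels says that the replicate numbers mark a shared animal or that each array came from a separate animal. The p-values therefore measure the spread between these samples.

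A total of 33 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with limma's fry. The lists covered the engineered loci, the Cdk4/6-Rb axis, S phase and E2F targets, G2/M and FoxM1 targets, p53 targets, DNA damage repair, luminal urothelium, basal and squamous keratinocytes, epithelial junctions, mesenchymal transition, smooth muscle, fibroblast and matrix, endothelium, T and NK cells, B and plasma cells, macrophages and monocytes, and neutrophils. The others were interferon response, MHC and antigen presentation, inflammatory cytokines and senescence secretome, receptor kinases and PI3K pathway, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, neuroendocrine, nerve and Schwann cells, adipocytes, skeletal muscle, lung, liver, kidney, intestine and mesothelium, and metastasis and invasion. List levels are means over measured members on an array. A 2-sided exact permutation test of these means, adjusted over the lists within a comparison, was added after the data were seen. After this adjustment, a lone list at the smallest p the splits allow could pass only for tumour against normal.

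The groups, comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. Genes named are the 10 largest rises and falls among genes that pass and do not overlap between groups, or, where none pass, the 5 with the smallest p in each direction. The rule adds the engineered loci, and for each list that passes, the 3 members with the smallest p in its direction. Predicted genes, small RNAs and receptor repertoires were left out. It named 200 distinct genes; the text gives those that show each list best, and says where a gene was chosen after its values were seen.

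Alternatives fixed in advance were a fit on only the 2 groups compared, array weights, a trended and robust variance prior, removal of genes below the 40th percentile of all rows (a level of 5.10, leaving 19898 genes), renewed quantile normalisation, and centring of each array on its median. The others were the mean of all rows of a gene, every row on its own, a log2 difference of at least 1, the replicate number as a block, the palbo metastasis counted as a metastasis, and each array left out in turn. After the data were seen, a set of 8 arrays was defined by a spread above 0.30 in dim rows (mean level 4.5 to 5.0) and a highest correlation of deviations with any other array below 0.25, over 5317 rows with a mean of at least 7. Every comparison was repeated without these arrays and with the set as a term in the model. Those without treated bladders, of which the set holds none, were also repeated within it.

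The procedure was tested on simulated data with the real gene means, residual spreads and group sizes. With 100 genes given a log2 change of 2 in each comparison, 99 were recovered for tumour against normal, 94 for treated against tumour, 97 for metastasis against tumour, 89 for treated against normal and 93 for metastasis against normal. At a change of 1, the counts were 70, 58, 73, 63 and 71. Between 6 and 12 genes given no change were also called in each comparison. A list shifted by 0.5 was called in every comparison, with at most 1 other list. The simulated genes vary independently, which genes on real arrays do not. Each simulated gene also had the same spread on every array, while the real arrays differed in spread. The counts therefore do not show how many such changes the real fits could recover. Figures were drawn with matplotlib.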

Results

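The data are expression levels of 30142 genes on 20 arrays from CKO mice, in which floxed alleles, that of Rb1 among them, can be deleted by Cre recombinase and which lack p107 (Rbl1) per the labels. There were 5 arrays of normal bladders, 7 of bladders inoculated with a Cre adenovirus (tumour bladders), 4 of metastases and 1 of a sample titled as a palbociclib metastasis. The remaining 3 were bladders of mice treated with palbociclib, an inhibitor of Cdk4 and Cdk6, and the platinum compound CDDP (treated bladders). Palbociclib was given at 150 mg/kg each day over 28 days and CDDP at 6 mg/kg each week. Array medians lay between 5.11 and 5.48 on the log2 scale. The labels do not say where a metastasis was taken.

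The arrays fell into 2 kinds that did not follow the groups. On 8 of them (normal bladders 4, 5 and 6, tumour bladders 3, 4 and 5, and metastases 3 and 4), the means of gene lists and the bright genes given here lay close to their mean over all arrays. The macrophage list, for example, ran from 6.28 to 6.52 on these 8 arrays and from 5.69 to 7.92 on the other 12. Acta2, the smooth muscle actin, ran from 7.33 to 7.89 on the 8 and from 4.58 to 12.16 on the 12, and Upk1a, an uroplakin of the luminal urothelium, from 7.51 to 8.60 against 4.07 to 14.18. All 33 gene lists had a smaller spread over the 8 arrays, with a median SD of 0.0587 against 0.360. In dim rows the 8 arrays had the larger SD, 0.355 to 0.386, where the other 12 lay between 0.240 and 0.284 but for tumour bladder 1 at 0.347. Their deviations from the row means correlated at r = 0.210 at most with any other array, across genes, which are not independent replicates; each of the 12 had a partner at r = 0.260 or higher. The 8 arrays were singled out after their values were seen, in part by low correlations of their deviations with other arrays. Small list differences within them, and larger ones over the 12, partly follow from that choice. For the lists that passed, the pooled difference is followed by its value over the 12 arrays and over the 8. The 8 held no treated bladder. Xist, the RNA of the inactive X chromosome, was at 11.74 and 11.71 on normal bladders 1 and 2, the only normal ones among the 12 arrays, and at 5.43 to 5.87 on the tumour bladders and metastases among them. Eif2s3y, a gene of the Y chromosome, was at 4.695 and 4.756 on normal bladders 1 and 2 and between 5.59 (tumour bladder 1) and 6.43 (metastasis 1) on those tumour bladders and metastases, but for tumour bladder 6 at 4.655. The labels give no sex, and on the 12 arrays a difference in sex is not separated from tumour or metastasis against normal. On treated bladders 1, 2 and 3, Xist was at 7.10, 6.04 and 10.05 and Eif2s3y at 5.208, 5.569 and 5.428, the latter gene above its level on normal bladders 1 and 2 and below that on tumour bladder 1, which leaves the sex of the treated animals open. On treated bladder 3, the Y gene Kdm5d was at 4.819, between normal bladders 1 and 2 (4.769 and 4.903). The Y gene Uty was at 5.218 there, above both (4.842 and 5.013). On treated bladders 1 and 2 Kdm5d was at 5.191 and 5.348 and Uty at 5.482 and 5.605. Tumour bladder 6 was low in Xist (5.428) and also in Uty and Kdm5d (4.715 each), so these genes do not give its sex. All these genes were chosen after their values were seen.

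**Figure D1:**
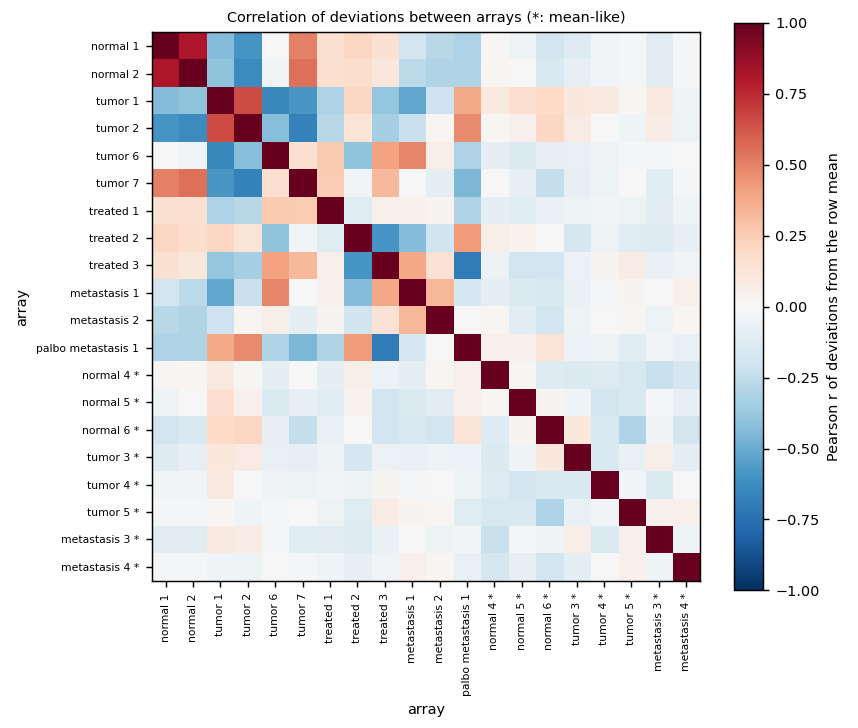
Pearson r of the deviations from the row mean, across genes, for each pair of the 20 arrays (both axes list the arrays; colour gives r; an asterisk marks the 8 arrays near the mean). The 8 arrays reach at most 0.210 with any other array, and each of the other 12 reaches at least 0.260. The 8 were chosen in part by a highest r below 0.25, so this gap partly follows from the choice.

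Tumour bladders were compared with normal bladders of CKO mice, for which the labels name no inoculation. Genes of the G2 and M phases of the cell cycle averaged 5.83 ± 0.36 (SD, n = 7) in tumour bladders and 5.50 ± 0.31 (SD, n = 5) in normal bladders, a log2 difference of 0.33, with all 36 measured members higher and 6 of 7 tumour arrays above the normal mean. Of these, tumour bladders 3, 4 and 5 (5.728, 5.752 and 5.704) lay near normal bladders 4, 5 and 6 (5.698, 5.723 and 5.77). S-phase and E2F target genes, which serve DNA replication, were higher by 0.27, with 30 of 31 members higher. Neutrophil genes averaged 5.97 ± 0.52 (SD, n = 7) against 5.45 ± 0.42 (SD, n = 5), with 18 of 19 members higher and 7 of 7 tumour arrays above the normal mean. Tumour bladders 3, 4 and 5 (5.709, 5.777 and 5.708), however, lay among normal bladders 4, 5 and 6 (5.778, 5.522 and 5.901). Smooth muscle genes, which encode the contractile apparatus of the bladder wall, averaged 6.31 ± 1.01 (SD, n = 7) against 6.88 ± 0.73 (SD, n = 5), with 21 of 22 members lower and tumour bladder 7 the only tumour array above the normal mean. That array was also the one below the normal mean for G2/M genes, at 5.28. Across genes, its deviations from the row means went with those of normal bladders 1 and 2 (r = 0.505 and 0.549). They went against those of tumour bladders 1 and 2 (r = -0.583 and -0.679), with r = 0.17 for tumour bladder 6.

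Among single members, Cdkn2a, which encodes the Cdk4 and Cdk6 inhibitor p16, was at 6.601 ± 0.41 (SD, n = 7) in tumour and 5.91 ± 0.37 (SD, n = 5) in normal bladders. Cdc20, an activator of the anaphase-promoting complex, was at 5.82 ± 0.50 against 5.22 ± 0.28, and Mcm2, a subunit of the replicative helicase, at 5.62 ± 0.33 against 5.21 ± 0.29. The neutrophil gene Stfa1 was at 6.11 ± 0.57 against 5.35 ± 0.41. Acta2 was at 7.57 ± 2.21 in tumour and 9.13 ± 1.81 in normal bladders. Tek, an endothelial receptor kinase, was at 5.90 ± 0.13 against 6.30 ± 0.44. The genes with the smallest p were Slfn10-ps, at 5.42 ± 0.28 against 4.76 ± 0.14, and Mepce, at 7.20 ± 0.20 against 6.76 ± 0.07, and among the lower genes Zfp174, at 5.05 ± 0.15 against 5.47 ± 0.16. Of the engineered loci, Rb1 was at 5.96 ± 0.34 against 6.13 ± 0.21 and Rbl1 at 6.62 ± 0.30 against 6.49 ± 0.22; where their probes lie relative to the altered parts of the genes is unknown, so the levels check no deletion. Other engineered genes were not analysed here. None of these genes passed the test.

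By limma, 0 of 30142 genes passed (smallest adjusted p = 0.998), with 1281 at an unadjusted p under 0.05, 721 of them higher (56.3%, and 54.5% with arrays centred on their medians), where chance gives 1507. The 2 groups did not overlap in 50 genes, where chance gives 76.1. Over the 12 arrays 0 genes passed and 1007 had an unadjusted p under 0.05, and over the 8 arrays 0 and 1624. By limma's camera, 10 of the 33 lists passed, 7 higher and 3 lower: G2/M genes (adjusted p = 2.3e-09), S-phase genes (6.3e-07), neutrophil genes (1.65e-06), smooth muscle genes (6.5e-06), endothelial genes (difference -0.14, 0.00057), inflammatory cytokines (0.26, 0.00097), the Cdk4/6-Rb axis (0.16, 0.0035), glycolysis and hypoxia (0.15, 0.022), adipocyte genes (-0.21, 0.038) and interferon response (0.14, 0.038). Each of these calls was lost, at an adjusted p = 0.847 with an estimated correlation. By fry 0 lists passed, and by the exact permutation test 0, with a smallest p of 0.0619 where the 792 splits allow 0.00126. Adjusted over the list alone, 0 members of any list passed.

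On the 12 arrays the G2/M difference was 0.75, the S-phase difference 0.62, the neutrophil difference 1.13 and the smooth muscle difference -1.35; over the 8 arrays they were -0.0022, -0.011, -0.0022 and -0.052. The other passing lists had, over the 12 and over the 8, endothelial genes -0.37 and 0.020, inflammatory cytokines 0.56 and 0.00087, the Cdk4/6-Rb axis 0.30 and 0.060, glycolysis 0.38 and -0.051, adipocyte genes -0.44 and -0.026, interferon genes 0.34 and -0.031. The 2 normal bladders among the 12 are those with high Xist. The adipocyte call ended with renewed quantile normalisation (-0.18, adjusted p = 0.0619), and the interferon call with arrays centred (0.13, 0.0537) or a term for the 8 arrays (0.14, 0.0532). No list passed within the 8 arrays, and 17 passed over the 12, which the choice of the 8 partly sets. Without tumour bladder 6 the neutrophil difference was 0.34 and the calls for inflammatory cytokines (0.081), the Cdk4/6-Rb axis (0.11), glycolysis (0.022), adipocyte (-0.12) and interferon genes (0.039) ended. Without tumour bladder 7 the smooth muscle difference was -0.92, and without normal bladder 1 or 2 it was -0.37. Without normal bladder 1, 6 lists passed, with endothelial (-0.068), glycolysis (0.11), adipocyte (-0.15) and interferon genes (0.11) no longer among them. The glycolysis (0.098), adipocyte (-0.16) and interferon (0.10) calls also ended without normal bladder 2, the adipocyte (-0.20) and interferon (0.14) calls without tumour bladder 3, and the interferon call (0.13) without tumour bladder 2.

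**Figure D2:**
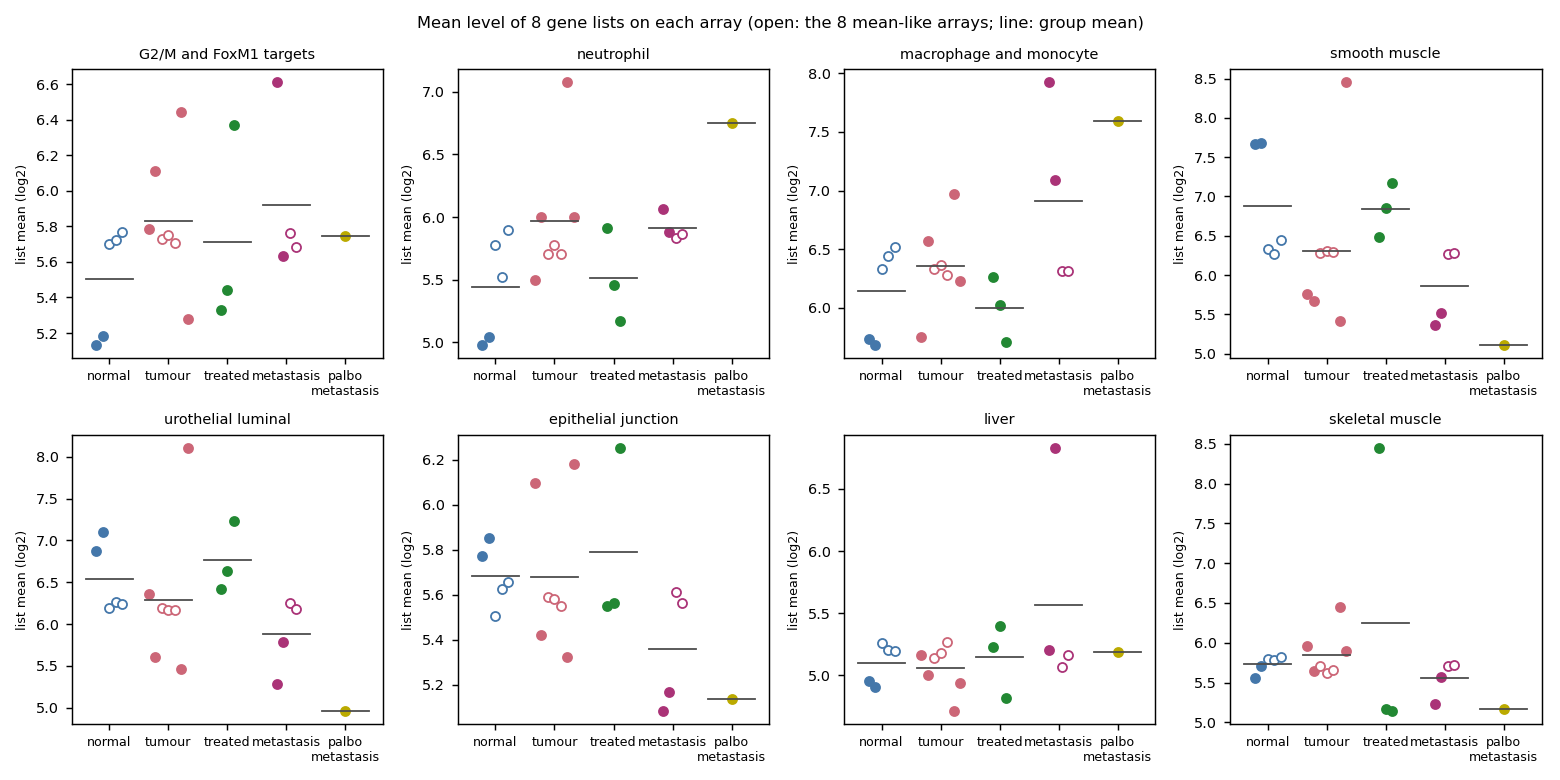
Mean log2 level of 8 gene lists on each array, by group; points are arrays, open points the 8 arrays near the mean, and lines the group means. Smooth muscle genes reach 8.45 on tumour bladder 7, skeletal muscle genes 8.44 on treated bladder 1, liver genes 6.83 on metastasis 2 and macrophage genes 7.92 on metastasis 1, while the open points stay together across groups.

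Treated bladders were compared with tumour bladders, to ask what differs under palbociclib and CDDP. Neutrophil genes averaged 5.51 ± 0.37 (SD, n = 3) in treated and 5.97 ± 0.52 (SD, n = 7) in tumour bladders, a difference of -0.45, with all 19 members and 3 of 3 treated arrays lower. Macrophage and monocyte genes were lower by 0.36 on the log2 scale, at 6.00 ± 0.28 against 6.36 ± 0.37, with 21 of 23 members lower. Smooth muscle genes averaged 6.84 ± 0.34 against 6.31 ± 1.01, with 21 of 22 members higher, and luminal urothelial genes 6.76 ± 0.42 against 6.29 ± 0.86, with 23 of 26 members higher. Both muscle and urothelial lists were above the tumour mean on 3 of 3 treated arrays. Genes of oxidative phosphorylation (26 of 26 members) and ribosomal proteins (15 of 15) were higher by 0.20 and 0.25, on 2 of 3 treated arrays.

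S-phase and E2F target genes averaged 5.89 ± 0.55 (SD, n = 3) against 6.00 ± 0.31 (SD, n = 7) and G2/M genes 5.71 ± 0.57 against 5.83 ± 0.36, each a difference of -0.11, with 31 of 31 and 32 of 36 members lower but 1 of 3 treated arrays above the tumour mean. Without treated bladder 3 these differences were -0.43 and -0.44. Without treated bladder 1 they turned to 0.062 and 0.078, and without treated bladder 2 to 0.046 and 0.022. Their calls also ended without tumour bladder 2 (-0.068 and -0.067) or 6 (-0.018 and -0.012), and without tumour bladder 7 the differences were -0.19 and -0.21. The Cdk4/6-Rb list was at 5.75 ± 0.35 against 5.80 ± 0.14 and did not pass (adjusted p = 0.33 by camera).

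Upk1b, an uroplakin, was at 12.50 ± 0.71 (SD, n = 3) in treated and 10.27 ± 2.36 (SD, n = 7) in tumour bladders, and Acta2 at 9.07 ± 1.70 against 7.57 ± 2.21. Cx3cr1, a chemokine receptor of monocytes, was at 6.97 ± 0.16 against 7.36 ± 0.45, and Cd3e, a chain of the T cell receptor complex, at 4.93 ± 0.04 against 5.32 ± 0.27. Atp5b, a subunit of ATP synthase, was at 7.47 ± 0.31 against 7.08 ± 0.37, and Rpl7, a ribosomal protein, at 7.36 ± 0.06 against 6.97 ± 0.43. The smallest p among higher genes belonged to the pseudogene Rpl31-ps12, at 10.51 ± 0.17 against 9.62 ± 0.67, and among lower genes to Tram1l1, at 3.92 ± 0.18 against 4.34 ± 0.21. Rb1 was at 6.07 ± 0.22 against 5.96 ± 0.34 and Rbl1 at 6.64 ± 0.88 against 6.62 ± 0.30. None of these genes passed.

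By limma 0 genes passed (smallest adjusted p = 1), 103 had an unadjusted p under 0.05 where chance gives 1507, 55 of them higher (53.4%, but 72.3% with arrays centred on their medians), and 39 did not overlap between groups where chance gives 502.4. Over the 12 arrays 0 passed and 101 had an unadjusted p under 0.05. By camera 18 lists passed, 8 higher and 10 lower: neutrophil (adjusted p = 8.9e-08), oxidative phosphorylation (8.9e-08), smooth muscle (1.3e-07), ribosomal proteins (4.5e-07), luminal urothelium (5.8e-07), macrophages (5.3e-06), T and NK cells (-0.14, 1.5e-05), skeletal muscle (0.41, 3.6e-05), inflammatory cytokines (-0.23, 7.2e-05), adipocytes (0.29, 8.1e-05), B and plasma cells (-0.17, 0.00017), interferon response (-0.17, 0.00026), MHC (-0.14, 0.00094), epithelial junctions (0.11, 0.0098), receptor kinases (0.065, 0.024), G2/M (0.027), S phase (0.0345) and kidney (-0.057, 0.0475). All 18 calls were lost, at an adjusted p from 0.398 to 0.780 with an estimated correlation. By fry and by the exact permutation test 0 passed; the smallest permutation p was 0.125 and the 120 splits allow 0.00833. Adjusted over the list alone, 0 members passed.

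Taken over the 12 arrays, the neutrophil difference was -0.63, the macrophage difference -0.38, the smooth muscle difference 0.52 and the urothelial difference 0.38, and 18 lists passed, without those of epithelial junction (0.032) and kidney genes (-0.071). The other passing lists had, over the 12, oxidative phosphorylation 0.17, ribosomal proteins 0.20, T and NK cell genes -0.13, skeletal muscle genes 0.26, inflammatory cytokines -0.30, adipocyte genes 0.32, B and plasma cell genes -0.22, interferon genes -0.23, MHC genes -0.15, receptor kinases 0.053, G2/M genes -0.19, S-phase genes -0.17. With array weights in limma, the calls ended for neutrophil (-0.11, adjusted p = 0.215), macrophage (-0.18, 0.165), urothelial (0.22, 0.215), inflammatory (-0.053, 0.255) and interferon genes (-0.038, 0.828), and junction and kidney genes turned to -0.042 and 0.039. The receptor kinase call also ended with dim genes left out (0.082, adjusted p = 0.0944), quantile normalisation (0.068, 0.0562) or a term for the 8 arrays (0.031, 0.0948), and the junction call with quantile normalisation (0.087, 0.0915). The kidney call ended in the fit on 2 groups (-0.057, 0.0885), with centring (-0.014, 0.0894) and with a term for the 8 arrays (-0.041, 0.114), and turned to 0.21 with dim genes left out. Without treated bladder 3 the neutrophil difference was -0.28 and the macrophage difference -0.21, and the calls ended for the urothelium (0.24), oxidative phosphorylation (0.060), ribosomal proteins (0.072) and T and NK cells (-0.057), while epithelial junction genes turned to -0.12 and kidney genes to 0.040. Without treated bladder 1 skeletal muscle genes turned from 0.41 to -0.69, and the adipocyte call (0.13) ended. Without treated bladder 2 the adipocyte (0.11), MHC (-0.075) and interferon (-0.12) calls ended, oxidative phosphorylation was higher by 0.42 and ribosomal proteins by 0.46. Without tumour bladder 6 the neutrophil difference was -0.27, and the inflammatory (-0.054), interferon (-0.067), MHC (-0.084) and junction (0.050) calls ended. Without tumour bladder 7 smooth muscle genes differed by 0.89, urothelial genes by 0.77, junction genes by 0.19 and receptor kinases by 0.11. Without tumour bladder 1 oxidative phosphorylation differed by 0.11, ribosomal proteins by 0.12, B and plasma cell genes by -0.11 and junction genes by 0.18. Skeletal muscle genes differed by 0.95 without treated bladder 2 and 0.96 without treated bladder 3, adipocyte genes by 0.61 and inflammatory genes by -0.15 without treated bladder 3, and T and NK cell genes by -0.21 without treated bladder 2. Junction genes differed by 0.23 without treated bladder 1 and 0.22 without treated bladder 2, oxidative phosphorylation by 0.12 without treated bladder 1, receptor kinases by 0.10 without tumour bladder 6 and 0.13 without treated bladder 2, and kidney genes by -0.091 without tumour bladder 6, -0.12 without treated bladder 1 and -0.090 without treated bladder 2. The junction call (0.067) ended without tumour bladder 2, the receptor kinase call without tumour bladder 1 (0.024) or 2 (0.035) or treated bladder 1 (0.038) or 3 (0.030), and the kidney call, which renewed quantile normalisation brought to 0.0017, without tumour bladder 1, 2, 3, 4 or 7 (-0.060 to -0.019).

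A share of genes that differed in tumour bladders and went the other way in treated bladders had been planned, but no gene passed to compute it on. Among the 1281 genes with an unadjusted p under 0.05 for tumour against normal, 96.1% had the opposite sign for treated against tumour, a set chosen after the data were seen. Both differences use the same tumour arrays, and arrays simulated with no effect gave a mean of 79.7% over 100 simulations. The simulated sets held 1508 genes on average, near the 1507 that chance gives. The spread of the simulated share is not given here, so 96.1% against 79.7% shows no excess by itself. With the tumour arrays divided into separate sets for the 2 differences, the median over 35 divisions was 55.3%, from 29.5% to 78.3%. On the 12 arrays, 97.0% of 1007 genes had the opposite sign, and the median over 6 divisions was 43.5%. Without treated bladder 2 the share was 82.2%.

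Metastases were compared with tumour bladders. Macrophage and monocyte genes averaged 6.91 ± 0.77 (SD, n = 4) in metastases and 6.36 ± 0.37 (SD, n = 7) in tumour bladders, a difference of 0.55, with 20 of 23 members higher and metastases 1 and 2 above the tumour mean. Epithelial junction genes averaged 5.36 ± 0.27 against 5.68 ± 0.33, with 22 of 23 members lower and 4 of 4 metastases below the tumour mean. Metastases 3 and 4 (5.613 and 5.561), however, lay near tumour bladders 3, 4 and 5 (5.591, 5.579 and 5.55). Basal and squamous keratinocyte genes differed by -0.28, with 21 of 26 members lower, luminal urothelial genes by -0.42, with 22 of 26 lower, and smooth muscle genes by -0.45, with 22 of 22 lower. Liver genes averaged 5.57 ± 0.84 against 5.06 ± 0.19; metastasis 2 stood at 6.83 and the other 3 metastases at 5.21 or lower.

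Lyz2, the lysozyme of macrophages and neutrophils, was at 11.23 ± 1.84 (SD, n = 4) in metastases and 9.40 ± 1.17 (SD, n = 7) in tumour bladders, and Csf1r, the receptor for macrophage colony-stimulating factor, at 6.68 ± 0.57 against 6.13 ± 0.29. Cldn4, a tight junction claudin, was at 5.198 ± 0.67 against 6.64 ± 1.03, Grhl2, an epithelial transcription factor, at 5.82 ± 0.37 against 6.43 ± 0.42, and Sfn at 4.85 ± 0.20 against 5.46 ± 0.33. Ahsg, which encodes the plasma protein fetuin-A, was at 8.15 ± 2.15 against 5.72 ± 0.60. Hnrnph2 had the smallest p, at 6.19 ± 0.23 against 5.45 ± 0.16, and among lower genes Defb5, at 5.52 ± 0.10 against 6.58 ± 0.32. Rb1 was at 5.98 ± 0.22 against 5.96 ± 0.34 and Rbl1 at 6.99 ± 0.89 against 6.62 ± 0.30, with metastasis 1 at 8.30. None of these genes passed over the 20 arrays.

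By limma 0 genes passed (smallest adjusted p = 0.207), 1745 had an unadjusted p under 0.05 where chance gives 1507, 728 of them higher (41.7%, which turned to 58.9% with arrays centred on their medians), and 152 did not overlap where chance gives 182.7. Over the 12 arrays, which leave metastases 1 and 2 against 4 tumour bladders, 3 genes passed and 1540 had an unadjusted p under 0.05: Ahsg, higher by 4.68 ± 0.33 (SE; adjusted p = 0.0018), Lyz1, a lysozyme, by 3.57 ± 0.27 (0.0018), and Ctsk, cathepsin K, by 2.22 ± 0.17 (0.0018). Over all 20 arrays the same genes were at 2.43 ± 0.64, 1.97 ± 0.49 and 1.18 ± 0.30, each with an adjusted p = 0.841. Within the 8 arrays 0 passed and 1566 had an unadjusted p under 0.05. By camera 9 lists passed, 4 higher and 5 lower: macrophages (adjusted p = 7.4e-08), epithelial junctions (3.1e-05), liver (5.0e-05), basal keratinocytes (0.00030), luminal urothelium (0.0029), smooth muscle (0.0065), B and plasma cells (-0.14, 0.040), oxidative phosphorylation (0.11, 0.040) and S phase (0.10, 0.041). All were lost, at an adjusted p = 0.795 with an estimated correlation. By fry and by the exact permutation test 0 passed (smallest p = 0.0758; the 330 splits allow 0.00303). Adjusted over the list alone 2 members passed, Ahsg in the liver list and Sfn in the basal list.

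With the 12 arrays alone, the macrophage difference was 1.12, the junction difference -0.63, the liver difference 1.06, the basal difference -0.46 and the urothelial difference -0.84; over the 8 they were -0.0096, 0.013, -0.079, -0.082 and 0.039. The other passing lists had, over the 12 and over the 8, smooth muscle genes -0.88 and -0.017, B and plasma cell genes -0.24 and -0.020, oxidative phosphorylation 0.20 and 0.023, S-phase genes 0.22 and 0.0078. With array weights in limma, the calls ended for oxidative phosphorylation (0.090, adjusted p = 0.0608) and S-phase genes (0.073, 0.125). Both also ended with dim genes left out (0.11 and 0.11, adjusted p = 0.176 each), quantile normalisation (0.12 and 0.11, 0.154 each), centring (0.16 and 0.15, 0.0669 each) and the palbo metastasis counted as a metastasis (0.019, 0.649, and 0.078, 0.0935). The B cell call ended with dim genes left out (-0.125, 0.134), quantile normalisation (-0.096, 0.061) and the palbo metastasis counted in (-0.075, 0.190). No list passed within the 8 arrays and 14 passed over the 12, which the choice of the 8 partly sets. With 1 array left out, 16 passed without tumour bladder 6 and 14 without metastasis 4. Without metastasis 1 the macrophage difference was 0.22, the urothelial (-0.22), smooth muscle (-0.29), B cell (-0.13) and oxidative phosphorylation (0.00060) calls ended, and S-phase genes turned to -0.087. Metastasis 1 also had the highest levels of Cst12 (9.08, next array 6.395), Defb19 (6.907, next 4.978), Cst9 (6.674, next 5.478) and Clu (9.225, next 7.424), genes with known expression in the male reproductive tract, chosen after their values were seen. Without metastasis 2 the liver (0.088), smooth muscle (-0.34) and B cell (-0.11) calls ended. Without tumour bladder 7 the urothelial (-0.12), smooth muscle (-0.095) and S-phase (0.024) calls ended. The oxidative phosphorylation call also ended without tumour bladder 1 (0.023), 2 (0.061) or 5 (0.096), the B cell call without 1 (-0.081) or 2 (-0.10), and the S-phase call without 1 (0.10), 3 (0.090), 4 (0.088) or 5 (0.089). Oxidative phosphorylation differed by 0.18 and 0.19 without tumour bladders 6 and 7, and S-phase genes by 0.19 without tumour bladder 6 and by 0.17, 0.16 and 0.17 without metastases 2, 3 and 4.

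**Figure D3:**
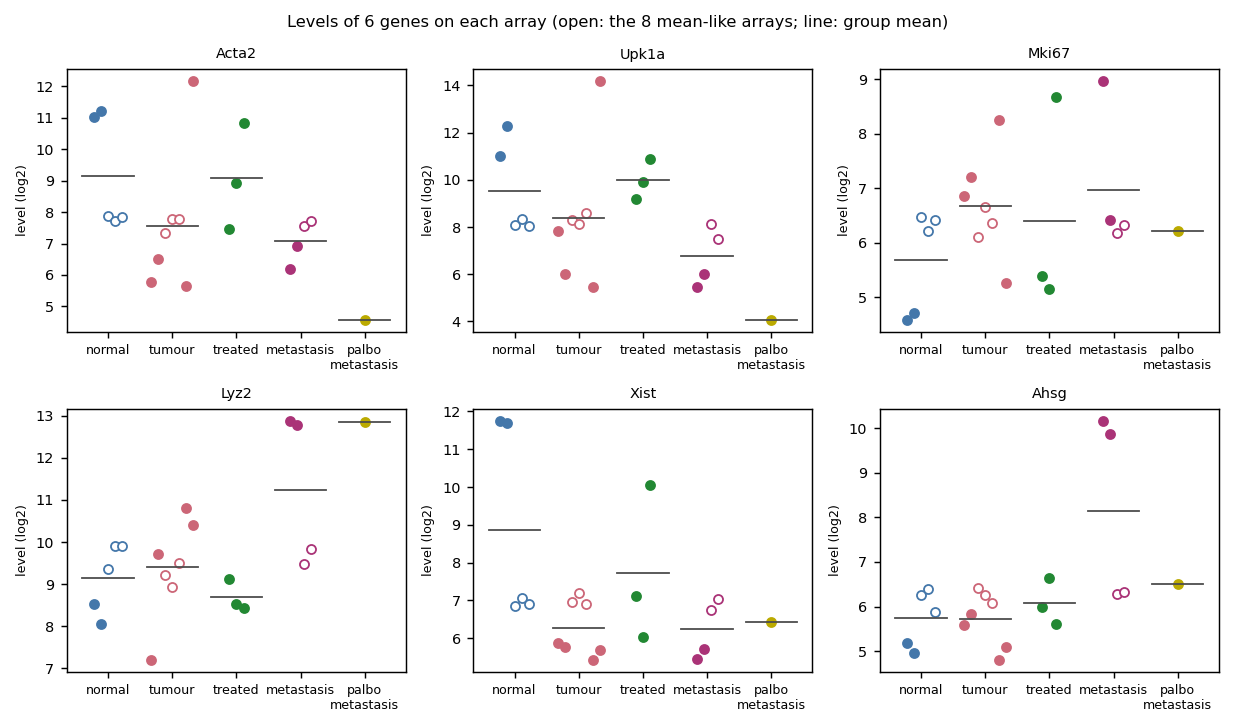
Log2 levels of 6 genes on each array, by group; points are arrays, open points the 8 arrays near the mean, and lines the group means. Ahsg lies at 10.16 on metastasis 1 and 9.87 on metastasis 2, and Xist between 6.74 and 7.19 on the 8 arrays, where the other 12 run from 5.43 to 11.74.

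Treated bladders were compared with normal bladders, to ask what differs from normal tissue after treatment. G2/M genes averaged 5.71 ± 0.57 (SD, n = 3) in treated and 5.50 ± 0.31 (SD, n = 5) in normal bladders, with 35 of 36 members higher but 1 of 3 treated arrays above the normal mean. S-phase genes were at 5.89 ± 0.55 against 5.73 ± 0.26, with 28 of 31 members higher, also on 1 of 3 arrays. Glycolysis and hypoxia genes were higher by 0.21, with 19 of 22 members higher, endothelial genes differed by -0.15, with 18 of 19 lower, and fibroblast and matrix genes by -0.15, with 20 of 23 and 3 of 3 arrays lower. For fibroblast and matrix genes the treated arrays (6.916, 6.773 and 6.913) lay near normal bladders 4, 5 and 6 (6.76, 6.91 and 6.902). Skeletal muscle genes averaged 6.25 ± 1.90 against 5.73 ± 0.11, with treated bladder 1 at 8.44.

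Gapdh, an enzyme of glycolysis, was at 10.22 ± 0.73 (SD, n = 3) in treated and 9.64 ± 0.14 (SD, n = 5) in normal bladders, and Cdkn1a, the Cdk inhibitor p21, at 6.77 ± 0.46 against 6.35 ± 0.27. Cdk4, a target of palbociclib, was at 7.07 ± 0.96 against 6.53 ± 0.20, but its difference of 0.54 was -0.016 without treated bladder 3. Tek was at 5.97 ± 0.34 against 6.30 ± 0.44 and Lum, a matrix proteoglycan, at 7.65 ± 0.20 against 8.38 ± 1.01. Krt19, a keratin, was at 6.84 ± 0.76 against 6.25 ± 0.21. The smallest p among higher genes belonged to the pseudogene Ldha-ps2, at 6.62 ± 0.66 against 5.78 ± 0.30, and among lower genes to Zfp354b, at 5.26 ± 0.07 against 5.81 ± 0.19. Rb1 was at 6.07 ± 0.22 against 6.13 ± 0.21 and Rbl1 at 6.64 ± 0.88 against 6.49 ± 0.22. None of these genes passed.

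By limma 0 genes passed (smallest adjusted p = 1), 108 had an unadjusted p under 0.05 where chance gives 1507, 63 of them higher (58.3%, but 74.6% with arrays centred on their medians), and 196 did not overlap where chance gives 1076. Over the 12 arrays, with 2 normal bladders, 0 passed and 247 had an unadjusted p under 0.05. By camera 14 lists passed, 10 higher and 4 lower: G2/M (adjusted p = 7.9e-07), skeletal muscle (3.3e-06), glycolysis (9.3e-06), endothelium (2.1e-05), S phase (7.8e-05), oxidative phosphorylation (0.14, 0.00024), T and NK cells (-0.092, 0.0012), luminal urothelium (0.23, 0.0037), ribosomal proteins (0.15, 0.0056), epithelial junctions (0.11, 0.0063), basal keratinocytes (0.11, 0.0063), the Cdk4/6-Rb axis (0.11, 0.0065), fibroblasts (0.030) and MHC (-0.089, 0.0345). All were lost, at an adjusted p from 0.812 to 0.830 with an estimated correlation. By fry and by the exact permutation test 0 passed (smallest p = 0.286; the 56 splits allow 0.0179). Adjusted over the list alone 0 members passed.

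Treated bladder 3, the treated array with Xist at 10.05, decided most of these values: without it 5 lists passed, G2/M genes turned to -0.12, S-phase genes to -0.16, the Cdk4/6-Rb axis to -0.087, junction genes to -0.12, basal genes to -0.068, ribosomal proteins to -0.029 and urothelial genes to -0.0059. The calls for endothelium (-0.077), glycolysis (0.070), oxidative phosphorylation (0.0026), T and NK cells (-0.014) and fibroblasts (-0.17) ended without it too. Treated bladder 3 also had the lowest median of any array (5.106). Across genes, its deviations went with those of tumour bladder 6 (r = 0.405) and metastasis 1 (r = 0.388). They went against those of treated bladder 2 (r = -0.592). Which trait of this array lies behind these values was not tested. Without treated bladder 1 skeletal muscle genes turned to -0.57 and the oxidative phosphorylation (0.058), ribosomal (0.12) and MHC (-0.10) calls ended; without treated bladder 2 the fibroblast (-0.10) and MHC (-0.029) calls ended, and glycolysis differed by 0.40. Without normal bladder 1 the endothelial (-0.078), S-phase (0.092), Cdk4/6-Rb (0.088) and fibroblast (-0.056) calls ended and G2/M genes differed by 0.12; without normal bladder 2 they differed by 0.13, and the Cdk4/6-Rb (0.078) and fibroblast (-0.12) calls ended. Without normal bladder 4 the ribosomal (0.10), junction (0.062) and MHC (-0.091) calls ended, and without normal bladder 6 those of the urothelium (0.15) and MHC (-0.055). Leaving out treated bladder 1 or 2 gave 0.40 and 0.35 for G2/M genes, 0.33 and 0.32 for S-phase genes, 0.23 and 0.22 for junction genes and 0.19 and 0.23 for the Cdk4/6-Rb axis. Urothelial genes differed by 0.40 without treated bladder 1, endothelial genes by -0.23, and without treated bladder 2 oxidative phosphorylation and ribosomal proteins differed by 0.36 each, basal genes by 0.23, T and NK cell genes by -0.17 and skeletal muscle genes by 1.06. Without treated bladder 3 skeletal muscle genes differed by 1.07 and MHC genes by -0.14, without normal bladder 2 urothelial genes by 0.37 and S-phase genes by 0.093, without normal bladder 4 urothelial genes by 0.14, and without normal bladder 6 T and NK cell genes by -0.056. On the 12 arrays 13 lists passed, 7 of them among the 14; G2/M genes differed by 0.56, S-phase genes by 0.45, glycolysis by 0.37, endothelial genes by -0.35, and urothelial genes turned to -0.23, ribosomal proteins to -0.038 and junction genes to -0.024. The other passing lists had, over the 12, skeletal muscle genes 0.62, oxidative phosphorylation 0.061, T and NK cell genes -0.031, basal genes 0.031, the Cdk4/6-Rb axis 0.23, fibroblast genes -0.39, MHC genes -0.046. With array weights in limma, the calls ended for G2/M (0.071, adjusted p = 0.335), S-phase (0.032, 0.554), endothelial (-0.12, 0.0558), T and NK cell (-0.061, 0.104), Cdk4/6-Rb (0.045, 0.554), fibroblast (-0.21, 0.106) and MHC genes (-0.052, 0.335) and ribosomal proteins (0.099, 0.124), while urothelial (-0.23), junction (-0.13) and basal genes (-0.00026) turned. The ribosomal call also ended with quantile normalisation (0.068, adjusted p = 0.410) and a term for the 8 arrays (0.015, 0.492).

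Metastases were compared with normal bladders. Macrophage and monocyte genes averaged 6.91 ± 0.77 (SD, n = 4) in metastases and 6.14 ± 0.40 (SD, n = 5) in normal bladders, a difference of 0.77, with 21 of 23 members and 4 of 4 metastases higher than the normal mean. Metastases 3 and 4 (6.314 and 6.318), however, lay below normal bladders 4, 5 and 6 (6.328, 6.44 and 6.522). Normal bladders 1 and 2 (5.738 and 5.688) lowered the normal mean. G2/M genes were higher by 0.42 (35 of 36 members) and S-phase genes by 0.37 (30 of 31), also on 4 of 4 metastases. Metastases 2, 3 and 4 lay near normal bladders 4, 5 and 6 here too. For G2/M genes they were at 5.635, 5.76 and 5.682 against 5.698, 5.723 and 5.77. For S-phase genes they were at 5.903, 5.93 and 5.901 against 5.904, 5.898 and 5.953. Smooth muscle genes averaged 5.86 ± 0.49 against 6.88 ± 0.73, with 22 of 22 members and 4 of 4 metastases lower. Metastases 3 and 4 were at 6.27 and 6.281, near normal bladders 4, 5 and 6 at 6.327, 6.262 and 6.444. Luminal urothelial genes averaged 5.88 ± 0.44 against 6.54 ± 0.43, with 23 of 26 members lower, and epithelial junction genes differed by -0.33, with 20 of 23 lower.

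Tlr7, a sensor of single-stranded RNA in myeloid cells, was at 8.54 ± 1.03 (SD, n = 4) in metastases and 6.79 ± 0.51 (SD, n = 5) in normal bladders, and Clec4d, a myeloid lectin receptor, at 7.15 ± 1.05 against 5.35 ± 0.63. Fcer1g was at 6.07 ± 0.46 against 5.30 ± 0.24 and C1qc, a complement chain made by macrophages, at 6.36 ± 0.29 against 5.77 ± 0.18. Rrm1, a subunit of ribonucleotide reductase, was at 6.53 ± 0.55 against 5.67 ± 0.34, Cdk6 at 6.23 ± 0.47 against 5.64 ± 0.15 and Cdk4 at 7.38 ± 0.50 against 6.53 ± 0.20. Upk1a was at 6.77 ± 1.25 against 9.55 ± 1.97, Cldn4 at 5.198 ± 0.67 against 6.76 ± 0.40, Trp63, a transcription factor of basal cells, at 5.13 ± 0.30 against 5.82 ± 0.35, and Pcp4 at 6.88 ± 0.86 against 8.49 ± 1.23. Zfp354b had the smallest p, at 5.001 ± 0.12 against 5.81 ± 0.19, and among higher genes Hspa13, at 6.23 ± 0.20 against 5.63 ± 0.16. Rb1 was at 5.98 ± 0.22 against 6.13 ± 0.21 and Rbl1 at 6.99 ± 0.89 against 6.49 ± 0.22. None of these genes passed over the 20 arrays.

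By limma 0 genes passed (smallest adjusted p = 0.528), 2082 had an unadjusted p under 0.05 where chance gives 1507, 933 of them higher (44.8%, which turned to 58.8% with arrays centred on their medians), and 860 did not overlap where chance gives 478.4. In a fit on only these 2 groups 1 gene passed, the predicted gene Gm3534, named after its value was seen, higher by 1.92 ± 0.17 (SE; adjusted p = 0.013), with an adjusted p = 0.717 in the fit on all arrays. Over the 12 arrays, which leave metastases 1 and 2 against normal bladders 1 and 2, 3 genes passed and 2011 had an unadjusted p under 0.05: Ahsg, higher by 4.95 ± 0.38 (SE; adjusted p = 0.00305), Lyz1 by 3.89 ± 0.31 (0.00305) and Ctsk by 2.29 ± 0.20 (0.0050). Over all 20 arrays Ahsg, Lyz1 and Ctsk were higher by 2.42, 1.85 and 1.29, each with an adjusted p = 0.717. Within the 8 arrays 0 passed and 1581 had an unadjusted p under 0.05. By camera 15 lists passed, 10 higher and 5 lower: macrophages (adjusted p = 1.1e-10), G2/M (1.1e-10), smooth muscle (6.5e-10), S phase (1.0e-09), luminal urothelium (5.5e-05), junctions (0.00019), glycolysis (0.26, 0.00025), the Cdk4/6-Rb axis (0.23, 0.00073), endothelium (-0.19, 0.00082), neutrophils (0.47, 0.00087), liver (0.46, 0.0022), inflammatory cytokines (0.21, 0.010), MHC (0.28, 0.014), basal keratinocytes (-0.27, 0.019) and DNA damage repair (0.10, 0.029). All were lost, at an adjusted p = 0.574 with an estimated correlation. By fry and by the exact permutation test 0 passed (smallest p = 0.0159; the 126 splits allow 0.00794). Adjusted over the list alone 6 members passed, 2 of them in the macrophage list.

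On the 12 arrays the macrophage difference was 1.79, the G2/M difference 0.96, the smooth muscle difference -2.23, the S-phase difference 0.85, the urothelial difference -1.46 and the junction difference -0.69; over the 8 they were -0.11, -0.0092, -0.069, -0.0031, -0.015 and -0.0075. The other passing lists had, over the 12 and over the 8, glycolysis 0.60 and -0.024, the Cdk4/6-Rb axis 0.50 and -0.0035, endothelial genes -0.42 and -0.032, neutrophil genes 0.96 and 0.12, liver genes 1.09 and -0.10, inflammatory cytokines 0.55 and -0.061, MHC genes 0.55 and 0.020, basal genes -0.48 and -0.086, DNA repair genes 0.28 and -0.041. The 2 normal bladders among the 12 are those with high Xist. With array weights in limma, the MHC call ended (0.25, adjusted p = 0.0608). The DNA repair call ended with dim genes left out (0.095, 0.120) and with the palbo metastasis counted as a metastasis (0.079, 0.0754). No list passed within the 8 arrays and 18 passed over the 12, which the choice of the 8 partly sets. Without metastasis 1, 9 lists passed, the macrophage difference was 0.43, the G2/M difference 0.19 and the S-phase difference 0.18, and the glycolysis (0.13), Cdk4/6-Rb (0.12), inflammatory (0.091), MHC (0.083), basal (-0.21) and DNA repair (0.023) calls ended. Without metastasis 2 the liver (0.043) and basal (-0.24) calls ended, and without metastasis 4 the basal call (-0.27). Without normal bladder 1 the endothelial difference was -0.12, and the inflammatory (0.15) and DNA repair (0.070) calls ended, the latter also without normal bladder 2 (0.071).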

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

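All tests of explanations in this part, and the counts over other splits, were chosen after the results they concern had been seen. Single arrays whose list mean or gene level lay far from the rest of their group, by the ratio of the gap to the range, numbered 52 among 699 groups of values, where chance gives about 1 in 20, or 35. These were 20 lists and 32 genes, each the highest of its group unless given as lowest. On normal bladder 6 they were MHC and antigen presentation genes (6.58), Hey2 (5.37, lowest), Ifng (5.37) and Tram1l1 (4.23). For normal bladder 4 they were Rfc4 (5.92) and Rpl7 (7.04, lowest). Tumour bladder 6 stood apart in Cdk4/6-Rb axis genes (6.11), mesenchymal transition genes (7.44), neutrophil genes (7.07), inflammatory cytokines and senescence secretome genes (6.78), glycolysis and hypoxia genes (7.15), adipocyte genes (5.43, lowest), skeletal muscle genes (6.45), metastasis and invasion genes (6.79), Clec4e (6.33), Cxcl1 (5.92), Ldha (8.27), Mrps27 (6.18), Pgk1 (8.98) and Tnnc2 (8.13). On tumour bladder 7 they were urothelial luminal genes (8.1), smooth muscle genes (8.45), Acta1 (9.23), Acta2 (12.16), Camp (6.41), Ckm (7.57), Des (8.44), Fgfr2 (6.77), Krt19 (7.89), Pcp4 (9.92), Pgm5 (8.58), Tpm2 (8.78) and Upk1a (14.18). For tumour bladder 5 it was Cd3e (5.88). Tumour bladder 2 stood apart in H2-Ab1 (7.34). On metastasis 1 they were engineered loci (7.27), S phase and E2F target genes (6.68), G2/M and FoxM1 target genes (6.61), DNA damage repair genes (5.83), MHC and antigen presentation genes (7.31), oxidative phosphorylation genes (6.99), neuroendocrine genes (4.99, lowest), Bub1 (5.93) and H2-DMa (5.74). For metastasis 2 they were liver genes (6.83), intestine and mesothelium genes (5.64) and Alb (9.4). Metastasis 3 stood apart in Krt15 (5.81), Pik3r1 (6.86, lowest) and Pkp1 (5.1). On metastasis 4 they were Mpo (5.21) and Tmem255b (5.48). Tumour bladders 6 and 7 held 14 and 13 of the 52.

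The 8 arrays whose list means lie near the mean of all arrays come from 3 groups, so no biological explanation was tested. In 105 rows where the other 12 arrays fall into a low and a high level at least 1.5 apart, with at least 3 arrays on each side, the 8 arrays lay at a median 0.381 of the way from low to high (0.326 to 0.477 by array), where a signal lost wholly to background would lie at the low level; RNA pooled from the other samples would lie near the log2 of their mean intensity, and the 8 arrays differed from it by a median of -1.47 (-1.59 to -1.15). Averaging of the other 19 arrays, or some of them, on the log2 scale would leave nothing beyond a weighted sum of these, but over 5317 bright rows the best such sum left a residual SD of 0.506 (0.484 to 0.585) on the 8 arrays, where it left 0.287 to 0.483 on the other 12. The 8 arrays had been chosen by low correlations over these same rows, which partly sets how their residual compares with that of the other 12. Averages with noise added, or of arrays not in the series, would lie at the share of arrays on the high side, and the position minus that share was -0.1 (-0.151 to -0.0656), which leaves these, and a partial loss of signal, open. The criterion for the 105 rows was loosened after a first one (levels at least 3 apart, at least 2 arrays on each side) left 3 rows, in which the values were 0.451, -3.15 and -0.0467.

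Liver genes averaged 6.83 on metastasis 2 and 4.72 to 5.39 on the other 19 arrays. Liver tissue in the sample would raise the abundant liver transcripts together: 13 of 18 members had their highest level there, among them Fgg at 10.16, Fgb at 9.95 and Alb at 9.40, but Ttr stood at 5.37 and Apoa1 at 5.70. A property shared by the metastases would raise the others too, and the highest of their list means was 5.21, but metastasis 1 is the only other one outside the 8 arrays, and of the members Ahsg (10.16 against 9.86) and Cyp2e1 (9.33 against 6.64) were higher on it than on metastasis 2. On metastasis 1, however, Fgg (4.325), Fgb (4.743), Fga (4.548), Alb (5.026), Hpx (4.487) and Apoa1 (4.667) had their lowest level of any array. The palbo metastasis, grouped apart and also outside the 8 arrays, had these genes at 4.697, 5.518, 5.379, 5.463, 5.133 and 4.996. For these genes the values argue against a property shared by the metastases. Ahsg and Cyp2e1 go the other way. On metastasis 1 they were high without the liver transcripts named above, which liver tissue would raise together. This argues against liver tissue as the source of both genes on that array. On metastasis 2, liver tissue and such a property cannot be told apart for both genes.

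Skeletal muscle genes averaged 8.44 on treated bladder 1 and 5.15 to 6.45 on the other 19 arrays. All 14 members had their highest level on this array, among them Tnnc2 at 10.31, Atp2a1 at 10.02 and Myh4 at 9.65, as striated muscle in the sample would give. An effect of treatment shared by the treated bladders is argued against by the other 2 treated arrays, which reached 5.17, below the lowest tumour bladder at 5.61. Striated muscle taken with the bladder stays open and may carry the skeletal muscle differences of treated bladders.

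The numbers of lists were set against other splits of the same arrays into groups of the same sizes, the real one included. At least as many lists came in 68 of 100 splits for tumour against normal (10 lists, highest other 21), 20 of 100 for treated against tumour (18, highest other 23), 74 of 100 for metastasis against tumour (9, highest other 24), 12 of 56 for treated against normal (14, highest other 18) and 20 of 100 for metastasis against normal (15, highest other 18). Chance cannot be excluded for any of these numbers of lists. The same splits say nothing about chance for genes: the real count by limma is 0 in each comparison (1281, 103, 1745, 108 and 2082 at an unadjusted p under 0.05, in the same order), which 100, 100, 100, 56 and 100 splits reach by construction. The highest numbers of genes in another split were 34, 1135, 54, 1 and 0. The 1135 genes came from the highest of 100 splits of treated and tumour arrays, where the median split called 0. Such a split may reflect a structure of the samples other than their groups, but this was not tested. Which arrays made it was not examined.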

How the results depend on the processing

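The fits without, within or with a term for the 8 arrays, the exact permutation test, and list counts with array weights or from 2 groups alone were chosen after seeing the data; the cause of the changes was not tested. In no fit on all arrays and all groups, nor with any 1 array left out, did a gene pass by limma; from 2 groups alone 1 gene passed for metastasis against normal, and without the 8 arrays 3 passed for metastasis against tumour and 3 against normal. The planned share of genes moving back has no value. Of the 66 list calls, direction and side of the threshold were kept in 66 with the mean of all rows, 62 with centring, 62 with a term for the 8 arrays, 60 with dim genes left out, 58 with quantile normalisation, 57 without the 8 arrays, 53 with the replicate block and 45 with array weights. Array signal over background limits dim genes. The number of lists by camera was 0 in all 5 comparisons with an estimated correlation, 0 in all 5 by fry and 0 in all 5 by exact permutation (0 for tumour against normal, 0 for treated against tumour, 0 for metastasis against tumour, 0 for treated against normal, 0 for metastasis against normal). By exact permutation a lone list could pass only for tumour against normal, because of the few splits elsewhere. Without the 8 arrays the number of lists by camera was 17 for tumour against normal and 14 for metastasis against tumour. Within them it was 0, 0 and 0. The choice of the 8 by low correlations partly sets these numbers. Array weights gave 7 for treated against normal and the replicate block 18 for tumour against normal. With 1 array left out, the lists ranged from 6 to 15 for tumour against normal, 13 to 20 for treated against tumour, 7 to 16 for metastasis against tumour, 5 to 15 for treated against normal and 9 to 16 for metastasis against normal, and the genes from 0 to 0 by limma. The share moving back was 82.16% without treated bladder 2. With the replicate block, calls ended for macrophage (-0.2131), inflammatory (-0.1174), G2/M (-0.111), S-phase (-0.1094) and kidney genes (-0.07154) for treated against tumour, smooth muscle (-0.2754) and S-phase genes (0.106) for metastasis against tumour, and T and NK cell (-0.0766), fibroblast (-0.1006) and MHC genes (-0.05725) for treated against normal. With the palbo metastasis counted as a metastasis, 8 lists passed against tumour and 16 against normal.

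Differences that turned, in log2: with array weights, Rbl1 (-0.4652), epithelial junction (-0.0417) and kidney genes (0.0386) for treated against tumour, and H2-Ab1 (0.03361), urothelial luminal (-0.2262), epithelial junction (-0.132) and basal genes (-0.0002645) for treated against normal. Kidney genes, treated against tumour, turned with dim genes left out (0.2141) and renewed quantile normalisation (0.001743), and Rb1, metastasis against tumour, with the mean of all rows (-0.1606). For treated against normal, the replicate block gave -0.02569 for urothelial luminal, -0.0352 for epithelial junction and -0.01748 for basal genes; without the 8 arrays urothelial luminal was at -0.2282, ribosomal proteins at -0.03844 and epithelial junction at -0.02449. With 1 array left out, ranges across 0 were, for treated against tumour, Ckm -0.5043 to 1.181, Eno3 -0.3097 to 0.5452, Actn3 -0.6517 to 1.027, skeletal muscle -0.6896 to 0.9583, G2/M and FoxM1 targets -0.4424 to 0.07769, S phase and E2F targets -0.4262 to 0.06166, Rbl1 -0.4945 to 0.3214, epithelial junction -0.1212 to 0.2294, kidney -0.1217 to 0.0397; for metastasis against tumour, Rbl1 -0.07064 to 0.5921, S phase and E2F targets -0.0872 to 0.1925; for treated against normal, Acta1 -0.2221 to 1.461, Myh1 -0.6603 to 1.427, Tnnc2 -0.6995 to 1.698, Aldoa -0.003378 to 0.7984, skeletal muscle -0.573 to 1.075, Rbl1 -0.361 to 0.4549, Ccnb2 -0.01659 to 0.5915, Ccna2 -0.04731 to 0.8776, Rrm1 -0.1096 to 0.5754, Ezh2 -0.2194 to 0.593, Jup -0.05546 to 0.3822, Dsc2 -0.01925 to 0.2603, Cdk4 -0.01634 to 0.8699, G2/M and FoxM1 targets -0.1154 to 0.4047, S phase and E2F targets -0.1567 to 0.3312, urothelial luminal -0.00591 to 0.402, ribosomal proteins -0.02856 to 0.3593, epithelial junction -0.125 to 0.2256, basal and squamous keratinocyte -0.068 to 0.2343, Cdk4/6-Rb axis -0.08686 to 0.2339.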

Other observations

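The lone palbo metastasis, which entered tests only in the alternative that counts it as a metastasis, had neutrophil genes at 6.754 (4 metastases 5.836 to 6.065), T and NK cell genes at 5.571 (4 metastases 5.105 to 5.362), macrophage genes at 7.590 (4 metastases 6.314 to 7.920), luminal urothelial genes at 4.965 (4 metastases 5.285 to 6.253), smooth muscle genes at 5.115 (4 metastases 5.360 to 6.281) and ribosomal proteins at 7.113 (4 metastases 7.493 to 7.858). Of the 33 lists, 9 lay above the range of the 4 metastases, 12 below and 12 within it. Metastases 3 and 4 are among the 8 arrays near the mean. Across genes, the deviations of the palbo metastasis went with those of tumour bladders 1 and 2 (r = 0.377 and 0.471) and treated bladder 2 (r = 0.425). They went against those of treated bladder 3 (r = -0.703). Whether its list levels belong to this metastasis or to the array was not tested.

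The following genes were chosen after their values were seen. On tumour bladder 6, Postn, a matrix protein, stood at 12.59, Ptgs2, a prostaglandin synthase, at 11.71, Mmp3, a matrix protease, at 10.88 and S100a8, a neutrophil protein, at 13.56. On metastasis 1, the proliferation marker Mki67 stood at 8.96, and Cst12, Defb19, Cst9 and Clu, which are known in the male reproductive tract, were also at their highest (9.084, 6.907, 6.674 and 9.225); treated bladder 3 had Mki67 at 8.67. Xist, the RNA of the inactive X chromosome, stood at 11.74 and 11.71 on normal bladders 1 and 2 and at 10.05 on treated bladder 3, between 6.74 and 7.19 on the 8 arrays near the mean, and at 5.43 on the lowest array; the labels give no sex.

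The lists that passed in no comparison had their smallest adjusted p by camera as follows: engineered loci (0.06, adjusted p = 0.435, treated against tumour), p53 targets (0.063, adjusted p = 0.0591, treated against tumour), mesenchymal transition (0.098, adjusted p = 0.0591, metastasis against tumour), neuroendocrine (-0.068, adjusted p = 0.0854, treated against tumour), nerve and Schwann cell (-0.18, adjusted p = 0.122, metastasis against normal), lung (0.098, adjusted p = 0.0683, tumour against normal), intestine and mesothelium (0.2, adjusted p = 0.118, metastasis against tumour), metastasis and invasion (0.22, adjusted p = 0.122, metastasis against normal).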
